A study of Mus musculus with 3 samples.

How the data were processed

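Each of 3 arrays compared total RNA of an adenoma (Cy5) with that of a late carcinoma (Cy3), per the labels, with the same dye orientation on every array, so a dye effect could not be fitted. The deposited value table holds log2 ratios, a reading taken from the values and the usual convention, since the log base and the numerator are not stated. The scanner, background correction, spot filter and normalization are not given in the sources used here. In each run of 812 rows the values were centred near 0. Of 38976 rows, 1 value was missing on array 2. The number of arrays limits the precision, and no intensity or background was used here.

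Rows were named through the platform annotation given for them: 22973 had exactly 1 gene symbol, 0 had several and 16003 had none. All 22973 matched a current gene by gene identifier in a table of the GRCm38.p6 assembly, used for names only, and 0 symbols changed. Rows without a symbol are unnamed here and can include control spots. Rows of a gene were averaged per array (5138 of 15056 genes had more than 1), unnamed rows stayed as probes, and 31058 units measured on 3 arrays were tested.

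The mean log2 ratio of each unit was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, eBayes, two-sided; prior degrees of freedom 4.60, prior SD 0.206), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Of 938 list entries in 32 gene lists, 809 were measured; lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it, adjusted over the 32 lists. Named genes were a fixed panel (Gata3, Esr1, Pgr, Foxa1, Elf5, Csn2, Wap, Krt8, Krt18, Krt5, Krt14, Mki67, Top2a, Cdh1 and Vim; Mki67 was not found by name), the 10 highest and 10 lowest means among named genes past the threshold with the same sign on all arrays, and per list up to 4 members past the threshold with the smallest p, or up to 2 with the largest mean where none passed. Other list members named in the text, such as Plin1, Csn3, Scd1, Fasn, Slc25a1, Kif2c and Birc5, were chosen after their values were seen. The design, the lists, this rule and the first alternatives below were fixed before the data were examined.

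Alternatives were median centring, scaling, units measured on at least 2 arrays, each row as its own probe, the first probe of a gene, a robust variance model, array weights, an adjusted p of 0.1, a 2-fold rule with no test, and leaving out each array. Added after the data were seen were a running median of 29 rows, centring on 979 olfactory and vomeronasal receptor genes, named genes alone, and the range of the receptor genes as a limit.

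Conditions for several tests of the closing section were changed after their values were seen, most of them towards leaving the question open. The median of the adipocyte list met the condition first written for added host fat when read on the mean of the arrays, though not on arrays 1 and 2, and a comparison with the receptor genes' median was then required as well. The poly(A) histone variants met a first condition, and variants on both sides of 0 were then counted as undecided. Tests of the milk protein and adipocyte lists against the receptor genes first counted genes above the highest receptor gene (5 and 2), which by the condition then written spoke against a probe effect for milk proteins; as these are the top genes of each list, the median of the whole list against 10000 random sets of receptor genes replaced the count. The test of proliferation against histone genes first compared the mean difference with its SD and was then held to each array, as its condition says. Held so, that condition was not met. A test of the spread over histone genes was set aside after its value was seen, because a wide spread does not separate the explanations.

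The fit was tested on simulated data for the comparison of adenoma with late carcinoma, with 31058 units and 50 changed at each of 4 sizes. At a log2 change of 0.5, 1, 2 and 3.5 it recovered 4%, 72%, 100% and 100%, and 4 unchanged units were called. The simulated units were independent, held no probe effect and changed far more rarely than units passed in the data. There, 25.1% of units passed, with unadjusted p up to 0.0126 and a median size of 0.60. The simulated recovery at small changes and the number of false calls therefore do not carry over to the data. With 200 random lists, 6 had a camera p under 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.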

Results

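Gene expression was compared between early and late stages of mammary tumour growth in mice that carry the polyoma middle T antigen under the MMTV promoter, a transgene that drives mammary tumours. Per the labels, premalignant lesions from young transgenic donors had been transplanted into hosts of the same strain, and outgrowths were taken as adenomas at 5 weeks or as late carcinomas at 18 weeks. Total RNA of an adenoma (Cy5) and of a late carcinoma (Cy3) was hybridised to each of 3 arrays of 2 channels, all with the same dye orientation. The value table gives 38976 log ratios per array, with medians of -0.012, -0.025 and -0.033. The number of arrays limits the precision, and spot intensities were not analysed here. The labels do not say whether the arrays come from separate animals, so p-values measure only the spread between these arrays, which may be technical.

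The ratios were read as log2 of Cy5 over Cy3, so a value above 0 is likely higher in the adenomas and a value below 0 likely higher in the late carcinomas. This reading rests on the dyes and channel order in the labels and on the usual convention, since neither the numerator nor the log base is stated, and every direction would turn if the ratio was formed the other way. Across 31058 genes and unnamed probes, Pearson's r between arrays was 0.610 for arrays 1 and 2, 0.744 for arrays 1 and 3 and 0.711 for arrays 2 and 3. Spearman's rho was 0.605, 0.681 and 0.700 for the same pairs. Genes are not independent replicates, so these values carry no p.

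The comparison asks which transcripts differ between the adenoma and the late carcinoma stage. Among named genes, the highest ratios on the adenoma side belonged to Fabp4, the fatty acid carrier of fat cells, and to genes of milk. Fabp4 had a mean log2 ratio of 3.49 ± 0.60 (SD, n = 3), an 11.2-fold ratio, and the alpha-S2 casein gene Csn1s2a had 3.46 ± 0.62. The whey acidic protein gene Wap had 2.44 ± 0.41. On the late carcinoma side, and again among named genes, the membrane protein genes Tm4sf1 and Cd63 had the lowest means, -1.66 ± 0.55 and -1.58 ± 0.24, and the simple epithelial keratin gene Krt19 had -1.16 ± 0.35. Each of these genes had the same sign on 3 of 3 arrays and a limma adjusted p of 0.00945 to 0.0117.

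By limma's moderated test with Benjamini-Hochberg adjustment, 7809 of 31058 genes and probes passed an adjusted p of 0.05, 4948 above 0 and 2861 below 0. Among 15055 named genes, 2412 passed above 0 and 1384 below 0. Among the named genes past the threshold, a mean of at least 2-fold was reached by 317 above 0 and 59 below 0. Of these, 57 of the 317 and 0 of the 59 were olfactory or vomeronasal receptor genes. The same sign on 3 arrays was seen for 60.6% of genes and probes, against 25% by chance. It was seen for 73.95% of the 979 receptor genes described below. The count of 7809 rests on array 3: without it, Fabp4 alone passed (mean log2 ratio 3.83, adjusted p = 0.0237), while 7758 genes and probes had an unadjusted p under 0.05, against 12545 with all arrays. Without array 1 or array 2, 7324 and 6997 passed.

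Olfactory and vomeronasal receptor genes, which serve smell in the nose, gave a background measured in the same way, though not the only possible one. Of 979 such genes, 426 passed above 0 and 26 below 0, or 46.2%, against 23.8% of the other named genes. For these genes, Pearson's r between arrays was 0.645 for arrays 1 and 2, 0.806 for arrays 1 and 3 and 0.702 for arrays 2 and 3. Agreement between arrays therefore does not by itself tell a stage difference from a probe or dye effect. The mean log2 ratios of the receptor genes had a median of 0.34 and ran from -0.88 to 1.33. Bitter taste receptor genes were alike, with a median of 0.24 and 42.9% of 28 past the threshold. Other families of restricted expression, looked at after the values were seen, went both ways. Hair keratin-associated protein genes leaned above 0, with a median of 0.17 and 9 of 28 past above 0 and 0 below. Prolactin family genes did too, with a median of 0.20 and 6 of 22 past above 0 and 0 below. Beta-defensin genes had a median of -0.0097 with 1 of 25 past the threshold. Hox genes had -0.16 with 13.9% past, and type I interferon genes -0.25 with 2 of 13 past, both below 0. Beyond the range of the receptor genes, 32 named genes passed above 0 and 102 below 0. Centring each array on the receptor genes took 0.41, 0.28 and 0.365 off every log2 ratio of arrays 1, 2 and 3 and left 11.9% of calls above 0, against 63.4% without it, so a mean above 0 but under the average of these amounts turns its sign under that centring.

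**Figure D1:**
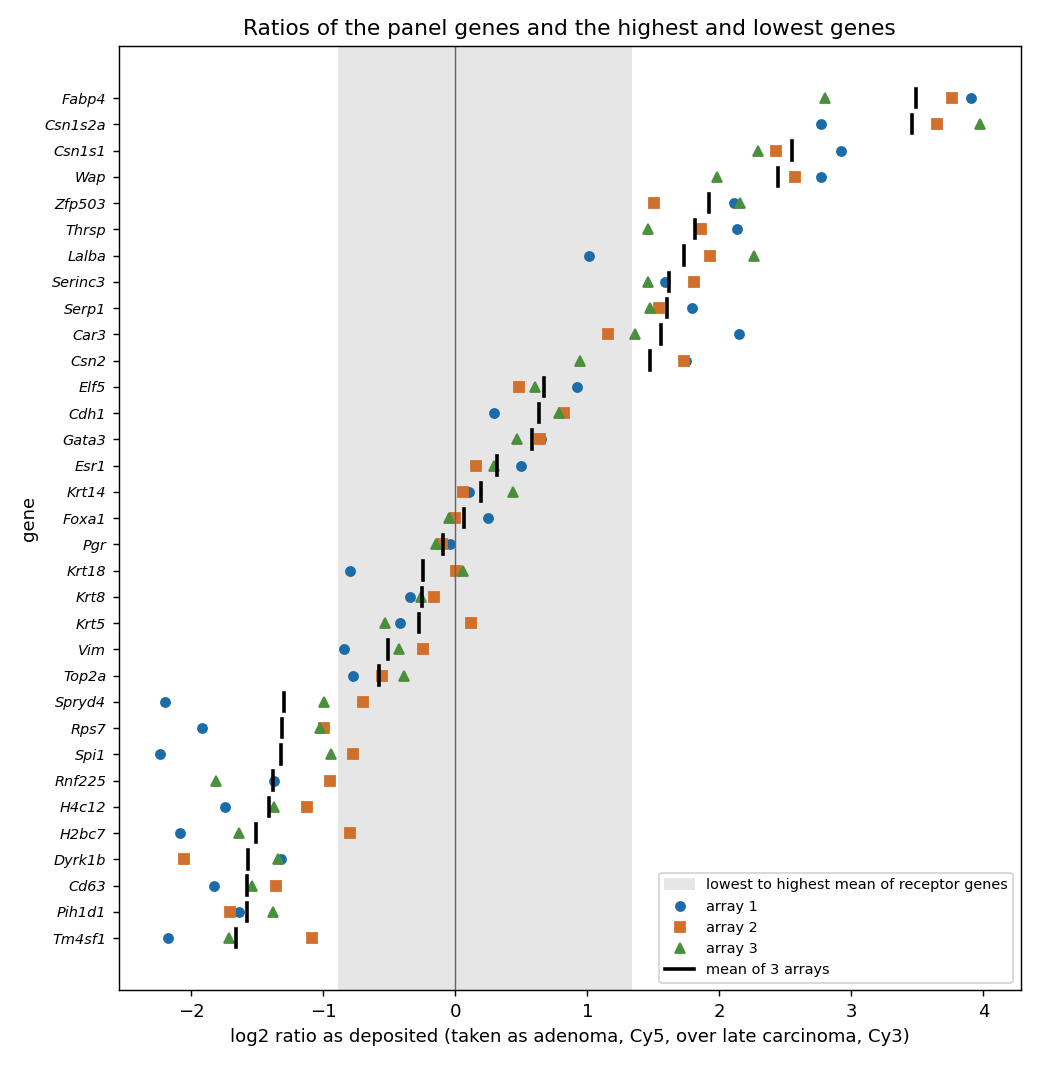
Log2 ratio (x axis) of the panel genes and of the highest and lowest named genes past the threshold (y axis), with a symbol per array and a black bar at the mean of 3 arrays. The grey band runs from the lowest to the highest mean of the 979 receptor genes, -0.88 to 1.33. Fabp4, Csn1s2a, Csn1s1, Wap and Csn2 have means above it, as do Zfp503, Thrsp, Lalba, Serinc3, Serp1 and Car3. The 10 lowest genes have means below it, and Gata3, Elf5, Cdh1, Top2a and Vim lie within it.

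Milk protein and secretory genes lay 0.84 above the other genes in mean log2 ratio (camera with a preset correlation of 0.01, limma adjusted p = 0.000363). The list did not pass with an estimated correlation (adjusted p = 0.789), though its estimate was only 0.0244. That setting also raised the camera p of fatty acid and sterol synthesis from 0.0279 to 0.129, with an estimate of -0.0295, below the preset. The loss can therefore not be put down to correlation between the milk protein genes. With an estimated correlation, camera takes its p from the residual degrees of freedom, and 3 arrays leave few of these. That setting therefore has little power here, and its result does not count for or against the milk protein shift. The median of the milk protein list was 0.62, against 0.34 for the receptor genes, and 23.4% of random sets of 19 receptor genes had a median as high on array 3. Of 19 measured, 12 passed above 0, 2 passed below 0 and 5 did not pass; adjusted over the list alone, 13 passed above 0 and 2 below 0. Csn1s1 had a mean log2 ratio of 2.55 ± 0.33, Lalba, the lactose synthase cofactor alpha-lactalbumin, 1.73 ± 0.65, Csn2 1.48 ± 0.46 and Csn3 0.99 ± 0.66. The lipid droplet gene Plin2 (-0.71 ± 0.46) and the lipase gene Cel (-0.44 ± 0.12) passed below 0. The list means were 0.95, 0.86 and 0.81 on the 3 arrays, and fry, which tests the list against no change and not against other genes, gave an adjusted p of 0.0350. The probes of Csn1s1 had means of 1.15 and 3.95.

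Adipocyte genes held 8 of 23 past the threshold above 0 and 1 below 0, and the same counts adjusted over the list alone. Besides Fabp4, Car3 (1.56 ± 0.53), the leptin gene Lep (0.62 ± 0.11) and the adiponectin gene Adipoq (0.53 ± 0.31) passed above 0, and Sncg (-0.44 ± 0.17) passed below 0. Lep did not pass with receptor centring (0.27, adjusted p = 0.0603). Plin1, which coats fat droplets, had 0.028 ± 0.23. The list's median was 0.16, below the receptor genes' median of 0.34, and its shift did not pass (camera adjusted p = 0.164). Among fatty acid and sterol synthesis genes, 7 of 31 passed above 0 and 2 below 0, or 10 and 2 adjusted over the list alone. Thrsp (1.82 ± 0.34), Srebf1 (1.36 ± 0.36), Scd1 (1.28 ± 0.55) and Fasn, the fatty acid synthase gene (0.67 ± 0.18), lay on the adenoma side, and the citrate carrier gene Slc25a1 (-0.73 ± 0.20) on the other. The shift of this list did not pass either (camera adjusted p = 0.164).

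Luminal epithelial genes went both ways, with 6 of 29 past the threshold above 0 and 3 below 0, and the same counts adjusted over the list alone. Gata3, a regulator of luminal identity, had a mean log2 ratio of 0.58 ± 0.10 (adjusted p = 0.0140), Elf5, which drives alveolar differentiation, 0.67 ± 0.23, Cdh1, the E-cadherin gene, 0.63 ± 0.29 and Aldh1a3 0.79 ± 0.19. Krt19, Tfap2c (-0.72 ± 0.25) and Erbb2 (-0.45 ± 0.20) passed below 0. Esr1 (0.32 ± 0.17, adjusted p = 0.0852), Pgr (-0.095 ± 0.051), Foxa1 (0.065 ± 0.16), Krt8 (-0.26 ± 0.088) and Krt18 (-0.24 ± 0.48) did not pass, though Esr1 passed with array weights (adjusted p = 0.0462) and Pgr, Krt8 and Krt18 passed below 0 with receptor centring (adjusted p = 0.0113, 0.00585 and 0.0302). Under the same centring Gata3 (0.23, adjusted p = 0.104) and Cdh1 (0.28, adjusted p = 0.131) no longer passed. The probes of Esr1 disagreed, with means of -0.097 and 0.73. None of 19 basal and myoepithelial genes passed, Krt5 having -0.28 ± 0.35 and Krt14 0.20 ± 0.21. The list shifts did not pass (camera adjusted p = 0.929 for luminal and 0.436 for basal genes), and Gata3, Elf5 and Cdh1 lie within the range of the receptor genes.

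Proliferation genes split. Of 41 measured, 14 passed above 0 and 5 below 0, or 14 and 6 adjusted over the list alone. The replication clamp gene Pcna (1.35 ± 0.17), Stmn1 (1.34 ± 0.37), E2f1 (1.12 ± 0.44) and Ube2c (1.10 ± 0.27) lay on the adenoma side, while Top2a (-0.58 ± 0.19), Kif2c (-0.67 ± 0.18) and Birc5 (-0.41 ± 0.088) lay on the late carcinoma side. The list mean was 0.19 and its median 0.007, and its shift did not pass (camera adjusted p = 0.485). Of 9 histone genes in the list fixed for them, 3 passed above 0 and 1 below 0 (camera adjusted p = 0.871), with H3f3a at 1.48 ± 0.38 and H4c9 at -0.78 ± 0.44. The probes of H4c9 had means of -1.61 and 0.047, so its direction turned with the first probe (adjusted p = 0.782). The 9 genes do not stand for all histones: of 51 replication-dependent histone genes, taken up after their values were seen, 3 passed above 0 and 30 below 0.

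Ribosomal protein genes lay below the other genes by a mean log2 difference of -0.37 (camera adjusted p = 0.00446), with 3 of 61 past the threshold above 0 and 6 below 0, or 1 and 6 adjusted over the list alone. With an estimated correlation of 0.598 between genes this call was lost (adjusted p = 0.802). Rps7 (-1.31 ± 0.53), Rpl36 (-0.76 ± 0.22) and Rpl21 (-0.73 ± 0.13) passed below 0, and Rps15a (0.68 ± 0.075) above 0. The list means were -0.81, -0.039 and -0.15, so array 1 decided the shift: without it the difference was -0.11 (adjusted p = 0.372).

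Growth factor and RAS-MAPK-PI3K signalling genes held 4 of 39 past the threshold above 0 and 11 below 0. Igfbp3 (-0.95 ± 0.32), Igf1, a growth factor of stroma and liver (-0.78 ± 0.26), and the feedback inhibitor gene Spry2 (-0.57 ± 0.15) passed below 0, and Btc, an EGF receptor ligand gene (0.62 ± 0.21), above 0. Basement membrane genes held 0 of 15 above 0 and 3 below 0: Col4a2 (-0.62 ± 0.15), Lamb1 (-0.55 ± 0.15) and Col4a1 (-0.40 ± 0.17). Col4a1 lost its call with median centring (adjusted p = 0.0505), with the running median (0.0517) and without array 1, 2 or 3 (0.109, 0.0624 and 0.187), and Btc lost its call with receptor centring (0.0716). Among fibroblast and fibrillar matrix genes, 1 of 32 passed above 0 and 4 below 0, with Col1a1, a chain of type I collagen, at -0.84 ± 0.45. Matrix proteases and inhibitors held 2 of 36 above 0 and 5 below 0. Of 21 epithelial-mesenchymal transition genes, 4 passed above 0 and 4 below 0, with Twist1 at -0.73 ± 0.087, Tgfb3 at 0.72 ± 0.015 and Vim at -0.51 ± 0.31, whose 8 probes had means from -0.92 to 0.61 and which did not pass without array 1 (adjusted p = 0.0875). Cell-cell junction genes held 10 of 24 above 0 and 2 below 0, with Cldn1 (0.78 ± 0.096) and Marveld2 (0.98 ± 0.36) above 0 and F11r (-0.74 ± 0.015) below 0. The camera adjusted p of these lists, in the order given, was 0.164, 0.372, 0.164, 0.159, 0.485 and 0.582, so none passed against the other genes. Against no change, fry gave an adjusted p of 0.00187 for basement membrane and 0.0308 for junctions, and of 0.00562 for fatty acid and sterol synthesis, 0.0399 for adipocytes, 0.00345 for interferon response and 0.0348 for the 9 histone genes. Adjusted over the list alone, the counts above and below 0 were 5 and 12 for growth factor signalling, 0 and 4 for basement membrane, 0 and 2 for fibroblasts, 2 and 5 for matrix proteases, 4 and 6 for epithelial-mesenchymal transition and 10 and 3 for junctions.

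**Figure D2:**
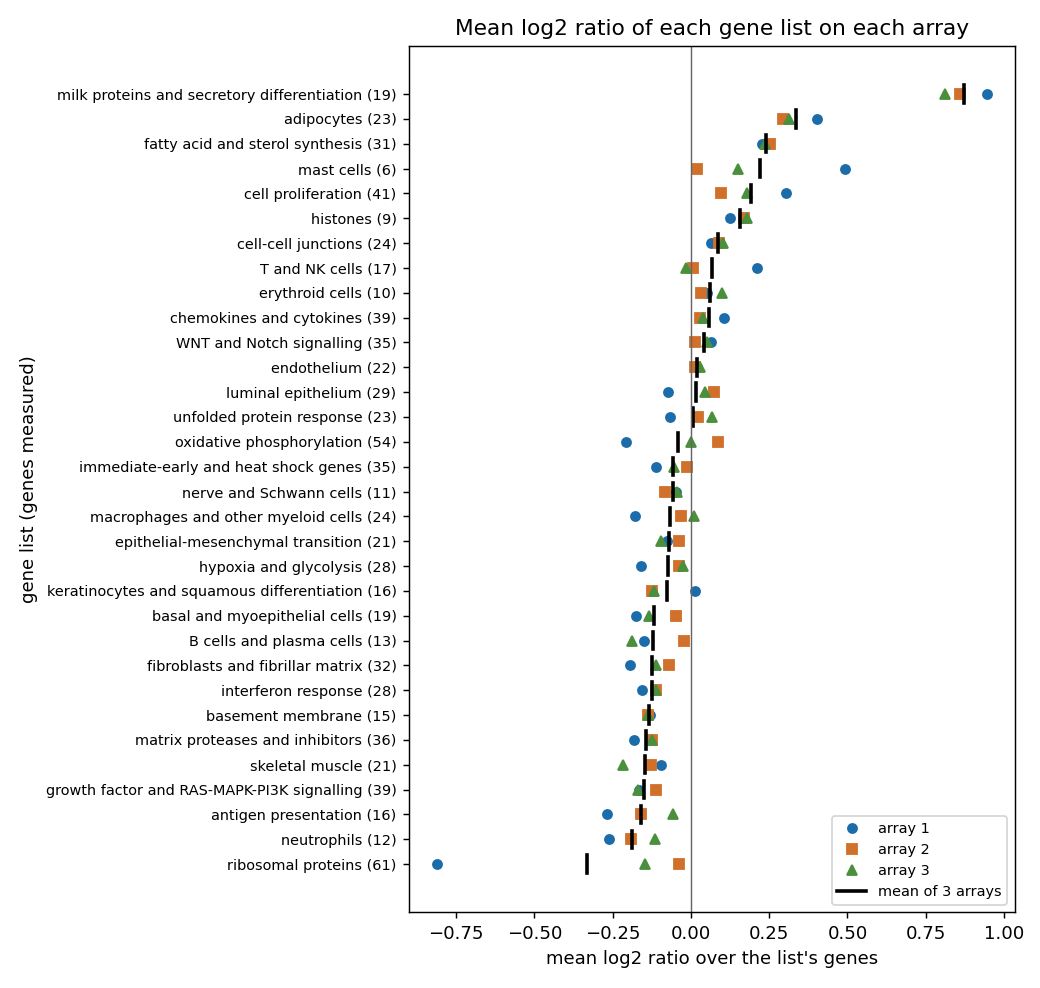
Mean log2 ratio of each gene list (y axis, with the number of genes measured) on each array (symbols) and over the 3 arrays (black bars). The milk protein list lies at 0.81 to 0.95 on the arrays, and ribosomal proteins lie at -0.81 on array 1 and at -0.039 and -0.15 on the others.

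Markers of other cell types passed about as often as named genes in general: 32 of 152 genes in 10 lists, or 21.1%, against 25.2% of all named genes. Macrophage and other myeloid genes held 3 of 24 past the threshold above 0 and 3 below 0, with the protease gene Ctss at 0.97 ± 0.26 and Itgam at -1.09 ± 0.27. T and NK cell genes held 2 of 17 above 0 and 1 below 0, B and plasma cell genes 1 of 13 and 1, mast cell genes 2 of 6 and 0, neutrophil genes 0 of 12 and 1, endothelial genes 2 of 22 and 0, erythroid genes 1 of 10 and 0, nerve and Schwann cell genes 1 of 11 and 2, skeletal muscle genes 2 of 21 and 4, and keratinocyte genes 3 of 16 and 3. The endothelial receptor gene Kdr had 0.69 ± 0.23, the neutrophil gene Lcn2 -1.20 ± 0.55 and the epidermal keratin gene Krt1 -1.25 ± 0.34. No list of these cell types passed camera, the lowest adjusted p being 0.164 for skeletal muscle. Adjusted over the list alone, the counts above and below 0 became 3 and 5 for macrophages, 2 and 0 for T and NK cells and 3 and 4 for keratinocytes, and did not change for the other lists of this paragraph.

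The remaining lists went both ways. Antigen presentation genes held 1 of 16 past the threshold above 0 and 3 below 0, with H2-Aa at 0.78 ± 0.27 and B2m, the light chain of class I molecules, at -0.61 ± 0.34 over 75 probes. The probe means of B2m ran from -1.33 to 0.62. Interferon response genes held 1 of 28 above 0 and 3 below 0, with Irf7 at -1.26 ± 0.49 and Ifih1 at 0.79 ± 0.14. Chemokine and cytokine genes held 6 of 39 and 1, with Il11 at 0.94 ± 0.026. Hypoxia and glycolysis genes held 3 of 28 and 4, with the glucose transporter gene Slc2a1 at -0.72 ± 0.19. WNT and Notch genes held 8 of 35 and 5, with Fzd1 at 1.20 ± 0.35. Unfolded protein response genes held 4 of 23 and 2, with the chaperone gene Canx at 0.91 ± 0.33. Oxidative phosphorylation genes held 8 of 54 and 5, and immediate-early and heat shock genes 5 of 35 and 6, with Fos at 0.66 ± 0.14 and Jun at -0.55 ± 0.13; Fos did not pass with receptor centring (0.31, adjusted p = 0.0546). The lowest camera adjusted p among these lists was 0.372, for interferon response. Adjusted over the list alone, the counts above and below 0 became 8 and 6 for WNT and Notch, 5 and 4 for the unfolded protein response and 5 and 8 for immediate-early genes, and did not change for the others of this paragraph or for the 9 histone genes. Means above 0 stood beside medians below 0 for T and NK cells (0.068 and -0.026), chemokines (0.058 and -0.044), WNT and Notch (0.042 and -0.016), the unfolded protein response (0.0076 and -0.099) and the 9 histone genes (0.16 and -0.059), and luminal and endothelial lists, whose mean lay -0.019 and -0.014 from the other genes, had the camera direction up.

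**Figure D3:**
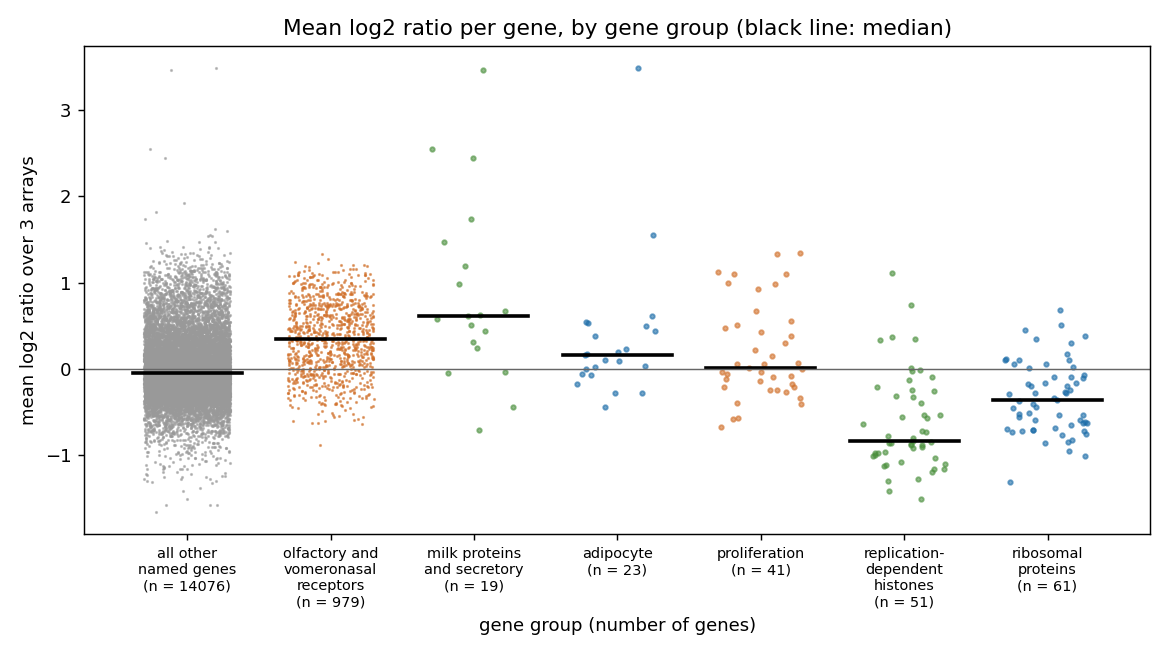
Mean log2 ratio over 3 arrays (y axis) of each gene (points) in 7 gene groups (x axis), with the median as a black line. The receptor genes have a median of 0.34 and the replication-dependent histone genes, a group taken up after its values were seen, one of -0.83.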

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

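The running median, receptor centring, receptor range and named-genes-alone settings were chosen after the data were seen; causes were not tested unless given. The 7809 calls (4948 above 0, 2861 below) stayed within 1.5 times in number under centring, scaling, 2-array units, the robust model and the running median. The first 3 of these settings could change little. Array medians were already near 0, and the median absolute deviations over all rows were 0.271, 0.265 and 0.2775. The 2-array rule tested 31059 units in place of 31058. The calls became 12036 (5386 below) with array weights, which weight array 3 most, and 19138 (2277 above, 16861 below) centred on receptor genes. With fewer units tested, named genes alone gave 4274 (2617 above, 1657 below); of the 3796 named calls among all units, 134 (32 and 102) lay beyond the receptor genes. An adjusted p of 0.1 gave 4927 below 0, and 2-fold on all arrays gave 85 (63 and 22). Leaving out an array gave 1 to 7324 calls, 1 to 4620 above 0 and 0 to 2840 below.

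With the first probe of each gene, Ctnnd1 (-0.078), Krt10 (-0.067) and H4c9 (0.047) changed sign and did not pass, and Cd2, Sfrp1, Mfap2 and Tnc kept their sign and did not pass (adjusted p = 0.0533, 0.155, 0.0702 and 0.23). Of 135 named genes, 125 no longer passed without array 3, 21 with receptor centring, 13 with the running median, 9 without array 1, 9 without array 2 and 1 (Col4a1) with median centring. All 125 kept their direction without array 3, 66 with a mean at least as large in size, and the median size was 0.77 with it and without it, so smaller ratios do not account for the loss. Arrays 1 and 2, which remain then, had the lowest Pearson's r of any pair, 0.610. Their spread was also the most unlike (SD over genes and probes 0.55 and 0.37, against 0.44 on array 3). Whether this accounts for the loss was not tested. Calls were gained by Esr1 with array weights and the running median (adjusted p = 0.0462 and 0.0389), by Krt14 with the running median (0.0338), by Pgr, Krt8, Krt18, Krt5 and Igfbp5 with receptor centring (0.0113, 0.00585, 0.0302, 0.0147 and 0.0157), by Igfbp5 with array weights (0.0412) and by Krt5 and Igfbp5 without array 2 (0.0475 and 0.00472). The number of shifted lists, 2, became 1 with array weights and with receptor centring, 1 to 2 with an array left out, and 0 with an estimated correlation. With 3 arrays the estimated setting has little power, as said for the milk protein list. Fry asks another question, whether a list differs from no change, and called 7, milk proteins and the 6 lists named with their values above. The milk protein shift of 0.84 kept its direction throughout and did not pass with an estimated correlation (adjusted p = 0.789). The ribosomal shift of -0.37 did not pass with array weights (adjusted p = 0.127; shift -0.37), receptor centring (0.288; -0.37) or an estimated correlation (0.802; -0.37), and ran from -0.53 to -0.11 with an array left out. Its mean of -0.33 did not pass fry against no change (adjusted p = 0.389). Signal over background was not analysed here. Each ratio already pairs the stages within an array, so no further block was fitted.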

Other observations

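Tests of gene lists against the receptor genes and the tests on 51 histone genes were chosen after the values were seen, and the condition for host fat was tightened then. By their means, 32 of the named genes past the threshold lay above the highest receptor gene and 102 below the lowest. Above it were Zfp503 (mean log2 ratio 1.92 ± 0.37, SD, n = 3), the endoplasmic reticulum gene Serp1 (1.60 ± 0.17) and Serinc3 (1.62 ± 0.18). Below it were Pih1d1 (-1.58 ± 0.17), Dyrk1b (-1.57 ± 0.42), Rnf225 (-1.38 ± 0.43), the myeloid transcription factor gene Spi1 (-1.32 ± 0.80) and Spryd4 (-1.30 ± 0.80). All had limma adjusted p values from 0.00959 to 0.0195 and the same sign on 3 of 3 arrays. The mean of Gata3, Esr1, Pgr and Foxa1 minus that of Krt8, Krt18, Epcam and Cdh1 was 0.15 with an SD of 0.38 between arrays; array 1 had 0.59 and the others -0.080 and -0.051, so without array 1 it turned to -0.065.

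The first pattern is the number of genes past the threshold, 7809, with 46.2% of receptor genes among the calls. A smooth effect of position in the table is argued against as the whole source, since 6930 genes and probes passed after a running median was subtracted, 6151 of them among the 7809. Effects tied to the probe, such as a dye effect that no swap cancels, may account for a large part: deviations of probes from their own gene's mean correlated between arrays with a median Pearson r of 0.652 across 13055 probes of 5138 genes, and their SD of 0.292 was as large as that of the gene means, 0.292. The gene means hold averaged probe deviations themselves, so these SDs do not weigh probe effects against gene effects. Splice forms and cross-hybridisation give such probe deviations too and were not told apart from dye. Turning the sign of an array gives 4 patterns, too few for a share under 0.05; the real one (1 of 4 with as many calls) gave 7809 and the highest other 0.

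The second pattern is the height of milk protein and adipocyte genes on the adenoma side. A probe effect of the size seen in receptor genes stays open for the milk protein list: 3.39% of 10000 random sets of 19 receptor genes had a median as high as its 0.62, with 2% on array 1 and 0.29% on array 2 but 23.4% on array 3. For the adipocyte list, 93.4% of random sets of 23 receptor genes had a median as high, so a probe effect of that size could account for its median. This depends on the background chosen: bitter taste receptor genes had a median of 0.24, but beta-defensin genes -0.0097 and Hox genes -0.16. Without spot intensities it is not known whether the shift of the receptor genes applies to genes of fat cells. Single genes stood higher by their means, with 5 of 19 milk protein genes and 2 of 23 adipocyte genes above the highest receptor gene. Only 3 milk protein genes and 1 adipocyte gene lay above the highest receptor gene of every single array. Secretory differentiation in the adenomas is an untested hypothesis. Host fat around the smaller outgrowths may contribute: the list's median of 0.16 was above 0 on all arrays and, on the mean, above the next cell type list (mast cells, 0.15). It was left open because T and NK cells were higher on array 1 (0.094 against 0.073) and mast cells on array 2 (0.23 against 0.18), and because the receptor genes had 0.34.

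The third pattern, noticed in the data, is a low ratio of histone genes, on which 3 tests were run. Of 51 replication-dependent histone genes, 30 passed below 0 and 3 above 0, with a median of -0.83 (-1.28, -0.44 and -0.67 on the arrays). Fewer dividing cells on the adenoma side would put the proliferation genes below 0 by about as much. Their medians were 0.018, -0.032 and 0.055 on the arrays, which argues against fewer dividing cells as the whole source. A part stays open: the median of proliferation genes lay 0.81 above that of the histone genes, but the 1.29, 0.41 and 0.725 on the arrays did not all exceed their SD of 0.45. The proliferation genes also went both ways. Labelling that differs for transcripts without a poly(A) tail could contribute and stays open: 5 variants with a tail had a median of -0.059 but ran from -0.26 to 1.48. The probe or dye effect raised for the first pattern was not tested for the histone genes and stays open too. The spread over histone genes (SD 0.56, against 0.40 over named genes) was also looked at and separates none of these.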
